A study of Drosophila melanogaster with 56 samples.

How the data were processed

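Whole males of 20 inbred Drosophila melanogaster lines, kept for 8 h or 20 h on control food or on the same food with tunicamycin, were profiled on 56 single-colour Agilent arrays labelled with Cy3. Per the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction 10.5.1.1, the tool that the submitters' processing notes also name. The deposited scanner values are spot intensities on a linear scale, as processed signal (background-corrected by the software), spot median and local background median, with flags for outliers, saturation and signal well above background. A deposited table of the series also holds intensities on a linear scale, with column medians from 722 to 13384. For the 18 arrays of the newer design its columns equalled the spot medians. For the 38 arrays of the older design at most 0.624% of values matched by spot number, and 2 columns held another array's values, so that the order of these values stays unknown. No centring was found in that table, and it was not used for any result.

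Starting from the scanner values, control spots and spots with outlier flags were left out, and saturated spots were kept. The processed signal was taken to log2 and scaled by subtracting the 75th percentile of each array, and spots of a probe were averaged. The 2 array designs (43603 and 43602 spots) held 32162 different probes between them. Of these, 20166 probes had a gene, 18121 through a locus tag, 1246 through an older CG identifier and 140 through a RefSeq accession in the reference table, and 659 kept the CG identifier of the array. The other 11996 probes had no gene name here. Probes were kept when well above background on at least 50% of the arrays of at least 1 of the 4 groups, which left 31097 probes, 19922 of them with a gene. Each gene was represented by its brightest probe over all 56 arrays, chosen blind to group. This gave 13481 tested genes, of which 4310 had more than 1 probe, and 4.235% of gene values were missing. Where the probes of a gene listed in advance differed in direction, the text says so. Genes not well above background in a whole group are given without a fold.

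Tests were run with limma 3.58.1 in R 4.3.3, on the log2 scale, with moderated variances and Benjamini-Hochberg adjustment over all genes, and genes past an adjusted p of 0.05 are called changed. Tunicamycin was compared with control at 8 h (20 lines) and at 20 h (8 lines), with the line as a block. The change of the response from 8 h to 20 h was tested on the differences between tunicamycin and control in the 8 lines with both times, and 20 h was compared with 8 h on control food in the same 8 lines. Differences among lines were tested with an F test over the line terms, for expression at 8 h and for the response over both times. There was 1 array per line, time and treatment, and the number of arrays limits the precision. The p-values for treatment and time measure the spread of the differences between lines. Those of the F tests set the lines against the residual within a line, between its arrays or its times.

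The pairing comes from the labels, which name the line of each array. It was checked over the 4258 genes measured on every array: deviations from the group means of the tunicamycin and control arrays of a line correlated with r from 0.279 to 0.952 at 8 h and from 0.731 to 0.954 at 20 h. Of the 56 arrays, 53 were nearest to an array of their own line. The arrays of a line also shared a slide, so that this check does not separate line from slide.

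Slide (16 slides), scan day (4 days) and array design were read from the files, and scan day and design together define 5 batches. Of the slides, 12 held 1 line and 4 held 2 lines. Every tunicamycin array lay in slide position 2 or 4 and every control array in position 1 or 3, so that position and treatment cannot be told apart. In the 8 lines with both times the 8 h arrays lay in positions 1 and 2 and the 20 h arrays in positions 3 and 4, so that position and time cannot be told apart either.

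Before the data were examined, 28 gene lists, the rule for the genes named, the main tests and most alternatives were fixed. The lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 28 lists), again with an estimated correlation, and with fry. Called members were counted over all genes and adjusted over the list alone. Named genes are, for tunicamycin at each time, the 12 largest and 12 smallest log2 differences among called genes that moved the same way in at least 18 lines at 8 h or in 8 of 8 lines at 20 h. For the change of the response and for control food over time they are the 8 largest and 8 smallest called differences. For line differences they are the 10 genes with the largest SD of line means, or with the smallest p for the response. Up to 4 members of each list with the largest differences, and Hsc70-3, Gp93, Xbp1, crc, PEK, Ire1, Atf6, Herp, Hrd3, P58IPK and Alg7, could be given whatever their values. Other list members, and genes behind a count of 5 or fewer, were picked after their values were seen.

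A line score is the mean log2 difference, in 1 line, of the list members measured on both arrays. Spots with outlier flags were left out, so the members averaged can differ between lines and times. For ER folding, Gp93 was missing in RAL820 at 8 h, and P58IPK in RAL301 and Sil1 in RAL318 at 20 h. Scores were compared by Pearson and Spearman correlation with two-sided permutation tests, exact for 8 lines and with 1e+05 permutations for 20 lines. Alternatives covered the scaling, the background correction, the filter, the probe of a gene, the variance model, the line block, the slide and scan day as blocks, the correlation between genes, the lines included and the leaving out of each line. After seeing the array quality, spot medians in place of the deposited table, a background correction on spot medians, outlier-marked spots kept and the leaving out of doubted lines, of members of the starvation list and of each line for the scores and lists were added. The fits were tested on simulated data with 200 changed genes among 13481. Of genes changed by 1 on the log2 scale, 94.0% were recovered for 8 h, 74.6% for 20 h, 49.3% for the change of the response and 85.1% for control food. For both tests of line differences the size was instead the SD of random line effects. At an SD of 1, 97.0% were recovered for line differences and 44.8% for line differences in the response. At a size of 0.5, the shares were 77.6%, 22.4%, 5.97%, 46.3%, 83.6% and 8.96% in the same order. Of all calls, 8.59%, 0.787%, 7.62%, 6.71%, 4.59% and 2.06% were unchanged genes, which is above the 5% set for 8 h, the change of the response and control food. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were read with numpy 2.4.6 and pandas 2.3.3. No genome was used, so positions of genes and unnamed probes are not analysed here.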

Results

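Natural differences in the response to stress of the endoplasmic reticulum (ER) were measured in 20 inbred lines of the Drosophila Genetic Reference Panel, which are fly strains descended from 1 wild population. Males aged 3 to 6 days fed on agarose (1.3%) with sucrose (1%), without or with 12 µM tunicamycin, a drug that blocks the first step of N-glycosylation and so disturbs protein folding in the ER. RNA of whole flies was measured after 8 h in 20 lines and after 20 h in 8 of them (RAL208, RAL301, RAL318, RAL358, RAL375, RAL379, RAL712 and RAL820), with 1 array per line, time and treatment, 56 in all. The 75th percentile of the processed signal ranged from 2560.4 to 74839.5 between arrays, and 72.7% to 99.1% of spots were well above background. Outlier flags numbered 41 to 22893 spots per array and were most frequent in RAL301, RAL318, RAL375 and RAL820. Differences are tunicamycin minus control on the log2 scale unless stated otherwise, with the standard error (SE) of the limma fit and n lines.

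The first comparison asked which genes respond to 8 h of tunicamycin across the 20 lines. Ugt37A3, a UDP-glycosyltransferase of detoxification, rose by 3.09 ± 0.30 (SE, n = 20; 8.53-fold, adjusted p = 1.45e-06) and was higher in 20 of 20 lines. The glutathione S-transferase genes GstD2 (2.93 ± 0.38, n = 20), GstD10 (2.70 ± 0.27, n = 19) and GstD4 (2.33 ± 0.30, n = 19) rose in every line that measured them. Sil1, a nucleotide exchange factor for the main ER chaperone, rose by 2.39 ± 0.17 (n = 20, adjusted p = 1.74e-08). That chaperone, Hsc70-3 (BiP), rose by 0.85 ± 0.07, the ER Hsp90 Gp93 by 0.96 ± 0.10 and the co-chaperone P58IPK by 0.88 ± 0.08, each in all lines measured.

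Other genes with the largest rises at 8 h were CG13659 (2.04 ± 0.20, n = 18), CG11893 (1.91 ± 0.19, n = 20), CG42382 (1.74 ± 0.28, higher in 19 of 20 lines), Ugt37A2 (1.64 ± 0.20) and sel, which codes for a saposin-like ER protein (1.62 ± 0.12, adjusted p = 5.41e-08). CG2004 (1.52 ± 0.16, n = 19) and Ugt37C2 (1.47 ± 0.18, n = 20) completed the set. CG13659, CG11893 and CG2004 belong to a family of ecdysteroid kinase-like genes. AANATL3, an arylalkylamine N-acetyltransferase-like gene, was at −1.09 ± 0.18 (lower in 19 of 20 lines, adjusted p = 0.00117), CG14120 at −1.03 ± 0.18 and the maltase gene Mal-A8 at −1.01 ± 0.16 (lower in 20 of 20 lines). CG3739 (−0.88 ± 0.17) and CG31343 (−0.83 ± 0.13) were also lower in 20 of 20 lines. CG5767, CG10477, CG8562, CheB38b, CG4734, CheB38c and CG18538 lay between −0.87 and −0.72. The call of CG18538 ended with normexp background correction (−0.44).

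Of 13481 genes, 175 were higher and 204 lower at 8 h, and 95 of these changed by 1.5-fold or more (43 higher, 52 lower). Without the line as a block 31 genes were called (29 higher, 2 lower), and 13 of the named genes, among them Mal-A8, CG31343 and Herp, lost their call. The count was 206 with normexp background correction (111 higher, 95 lower) and 152 in the 8 lines that also had 20 h arrays (89 higher, 63 lower). Within scan batches 67 genes were called in 4 lines (51 higher, 16 lower), 15 in 3 lines (14 higher, 1 lower), 0 in another 3 lines (RAL335, RAL370 and RAL440) and 65 in 9 lines (51 higher, 14 lower), and a batch of 1 line gave no test.

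Transcripts of genes that regulate the unfolded protein response did not pass the test at 8 h. The activity of the proteins they code for was not measured. Xbp1, the transcription factor of the Ire1 branch, differed by 0.11 ± 0.07 (adjusted p = 0.662) and Ire1 itself by 0.08 ± 0.06. The stress kinase PEK differed by 0.32 ± 0.11 (n = 17, adjusted p = 0.20). Hrd3, of the ubiquitin ligase that clears ER proteins, differed by 0.15 ± 0.05 (adjusted p = 0.134) and passed with quantile scaling (0.17). The ATF4 homologue crc differed by 0.11 ± 0.10, and by −0.04 with quantile scaling. Atf6 was at −0.02 ± 0.08, and at 0.02 or 0.03 with quantile or median scaling. Probes disagreed in direction for Xbp1 (3 of 4 probes one way), crc (1 of 2), Ire1 (2 of 3) and Atf6 (1 of 2). Herp, a partner of that ligase, rose by 0.35 ± 0.07 (higher in 19 of 20 lines, adjusted p = 0.00323). Alg7, which codes for the enzyme that tunicamycin inhibits, differed by 0.24 ± 0.12 (n = 18, adjusted p = 0.50) and passed with quantile scaling (0.35).

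As groups, the genes of the secretory pathway rose at 8 h. Of 21 ER folding genes, 10 rose and 0 fell over all genes, and 16 rose adjusted over the list alone (median 0.28, camera adjusted p = 3.63e-32, and adjusted p = 0.000511 with an estimated correlation). Beside Sil1, CaBP1 rose by 1.26 ± 0.12 and the oxidase Ero1L by 0.96 ± 0.10. Of 13 genes of ER-associated degradation, Herp and Der-2 (0.28 ± 0.06) rose, and 3 adjusted over the list alone (adjusted p = 9.00e-05, and adjusted p = 0.0411 with an estimated correlation). Sec61beta, Sec63, Srp68 and twr were the 4 of 23 translocon and signal peptide genes that rose, with 11 adjusted over the list alone (adjusted p = 9.66e-14, and adjusted p = 0.00355 with an estimated correlation). Of 21 N-glycosylation genes, 6 rose, led by wol (0.49 ± 0.07), and 9 adjusted over the list alone (adjusted p = 2.01e-08, and adjusted p = 0.0231 with an estimated correlation). Of 23 genes of ER to Golgi transport, 7 rose, led by the coatomer gene beta'COP (0.49 ± 0.09), and 15 adjusted over the list alone (adjusted p = 8.68e-18, and adjusted p = 0.0128 with an estimated correlation).

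Amino acid genes of the kind that ATF4 regulates rose at 8 h, in 6 of 26 members over all genes and 11 adjusted over the list alone (median 0.13, adjusted p = 1.39e-10, and adjusted p = 0.0114 with an estimated correlation). Most members of this list are tRNA synthetase genes, and the rest belong to amino acid metabolism or stress. The 6 called were all tRNA synthetase genes, among them AspRS (0.57 ± 0.10), ValRS (0.49 ± 0.10) and SerRS (0.42 ± 0.08). Of 42 detoxification genes, 9 rose and 14 adjusted over the list alone (median 0.13, adjusted p = 9.66e-14, and adjusted p = 0.0411 with an estimated correlation). These 7 lists were the ones whose 8 h camera call held with an estimated correlation. Of 44 digestive enzyme genes, 8 fell and 19 adjusted over the list alone (median −0.19, adjusted p = 1.71e-12, but adjusted p = 0.0592 with an estimated correlation), with Mal-A8, Jon99Ci (−0.74 ± 0.13) and Mal-A6 (−0.64 ± 0.13) the lowest of those called. Medians within the 5 batches ran from −0.52 to −0.04 for the digestive list, 0.16 to 0.56 for ER folding, 0.07 to 0.36 for ER to Golgi transport and 0.07 to 0.25 for detoxification. Those of degradation (−0.04 to 0.20), translocon (−0.01 to 0.27), N-glycosylation (−0.09 to 0.24) and amino acid genes (−0.04 to 0.24) were below 0 in at least 1 batch.

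Further lists passed at 8 h with the preset correlation alone. The 11 genes of unfolded protein response signalling had a median of 0.11 with 0 called (adjusted p = 0.00125, and adjusted p = 0.134 with an estimated correlation). The 7 Turandot stress peptides had a median of −0.42 with 0 called (adjusted p = 0.00203, and adjusted p = 0.176 with an estimated correlation). The 88 ribosomal protein genes had a median of 0.11 with 0 called (adjusted p = 1.23e-08, and adjusted p = 0.502 with an estimated correlation), and their camera t turned to −0.623 with quantile scaling. Accessory gland markers (median 0.12, adjusted p = 0.000319) and muscle markers (median 0.13, adjusted p = 0.000376), 14 genes each with 0 called, both had adjusted p = 0.299 with an estimated correlation, and neither passed with quantile scaling. Of 8 Malpighian tubule markers, Nha1 fell (−0.16 ± 0.04), 3 adjusted over the list alone (adjusted p = 0.0083, and adjusted p = 0.115 with an estimated correlation). Within the 5 batches the medians turned in sign for signalling (−0.03 to 0.22), Turandot (−0.51 to 0.56), ribosomal (−0.32 to 0.73), accessory gland (−0.22 to 0.35) and muscle genes (−0.21 to 0.36), and ran from −0.30 to −0.02 for Malpighian tubule markers. Without RAL375 the medians of ribosomal, accessory gland and muscle genes were 0.05, 0.05 and 0.07, and without RAL301 that of Malpighian tubule markers was −0.05.

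The remaining lists did not pass at 8 h. Dcp-1, an effector caspase gene, fell by 0.26 on the log2 scale among 15 cell death and JNK genes (list adjusted p = 0.0738), 2 fell adjusted over the list alone, and the list passed with quantile scaling. Pepck1, of gluconeogenesis, rose by 0.38 ± 0.10 among 17 starvation and insulin genes, with 1 higher and 3 lower (Lip3, mag and sug) adjusted over the list alone (list adjusted p = 0.284). The glucosidase gene tobi fell by 0.51 among 17 lipogenesis and sugar genes, the 1 lower adjusted over the list alone (list adjusted p = 0.889). No member was called among cytosolic heat shock (adjusted p = 0.947), antioxidant (0.205), antimicrobial peptide (0.889), autophagy (0.971), proteasome (0.583) or circadian clock genes (0.327). The same held for markers of testis (0.201), female reproduction (0.583), fat body (0.393), neuron and eye (0.110) and hemocytes (0.602), and these lists also had 0 called adjusted over the list alone.

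The second comparison asked the same after 20 h in 8 lines. Ugt37A3 rose by 4.33 ± 0.09 (SE, n = 8; 20.2-fold, adjusted p = 2.64e-09) and Ugt37C2 by 4.02 ± 0.18. Sil1 rose by 3.58 ± 0.13 (n = 7), GstD2 by 3.95 ± 0.27 (n = 7) and GstD10 by 3.91 ± 0.12 (n = 7). The lysosomal alpha-mannosidase gene LManVI fell most among the genes that moved the same way in 8 of 8 lines (−5.98 ± 0.36, 63.2-fold, adjusted p = 1.18e-05). The digestive serine protease genes Jon99Fi (−6.04 ± 0.57, n = 6) and Jon99Ci (−4.94 ± 0.22, n = 7) fell as well.

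Other large rises at 20 h were in GstD4 (2.95 ± 0.28), the cytochrome P450 genes Cyp9b2 (2.53 ± 0.25) and Cyp28a5 (2.29 ± 0.23), Ugt37A2 (2.51 ± 0.27) and sel (2.26 ± 0.20). CG7381, the sterol transport gene Npc1b, GstD5, CG10184 and CG13658 rose by 2.21 to 2.04. Large falls were in CG31343 (−4.93 ± 0.32), CG17192 (−4.70 ± 0.47), LManIII (−4.62 ± 0.38), CG31089 (−4.19 ± 0.63) and Jon65Aii (−3.92 ± 0.40). Alp9, an alkaline phosphatase gene, was at −3.77 ± 0.62. CG8562, CG7542, CG3739, Jon66Ci and Jon25Bi lay between −3.72 and −3.40. Hsc70-3 rose by 1.17 ± 0.12, Gp93 by 1.69 ± 0.17, P58IPK by 1.49 ± 0.15 (n = 7) and Herp by 0.70 ± 0.14. Alg7 rose by 0.69 ± 0.12 (n = 6, adjusted p = 0.0125), a call lost when outlier-marked spots were kept (0.18). Xbp1 (0.38 ± 0.13, adjusted p = 0.208), crc (0.35 ± 0.17, n = 7), PEK (0.39 ± 0.12, n = 7) and Ire1 (0.30 ± 0.11, n = 6) did not pass, except Ire1 with outlier-marked spots kept (0.54). Nor did Hrd3 (0.15 ± 0.10, and −0.01 with normexp background correction or −0.05 with spot medians) and Atf6 (0.04 ± 0.13, n = 5, and −0.04 with median scaling), whose 2 probes disagreed in direction.

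At 20 h 287 genes were higher and 251 lower of 13481, and 434 changed by 1.5-fold or more (204 higher, 230 lower). Without the line as a block 139 genes were called (57 higher, 82 lower), and 8 of the named genes lost their call, among them GstD4, Jon25Bi and Herp. Lower genes also outnumbered higher ones without RAL301 (316 higher, 344 lower), without RAL712 (191 higher, 196 lower) and without the lines rich in saturated spots (333 higher, 365 lower). Within scan batches 775 genes were called in 4 lines (354 higher, 421 lower) and 213 in 3 lines (89 higher, 124 lower), and the batch of 1 line gave no test. Of the genes called at 8 h and at 20 h, 136 were higher at both times, where independent lists would share 3.73. A further 112 were lower at both times, against 3.80, and 0 were called in opposite directions. The arrays of the 2 times were separate, but 8 lines were common to both.

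**Figure D1:**
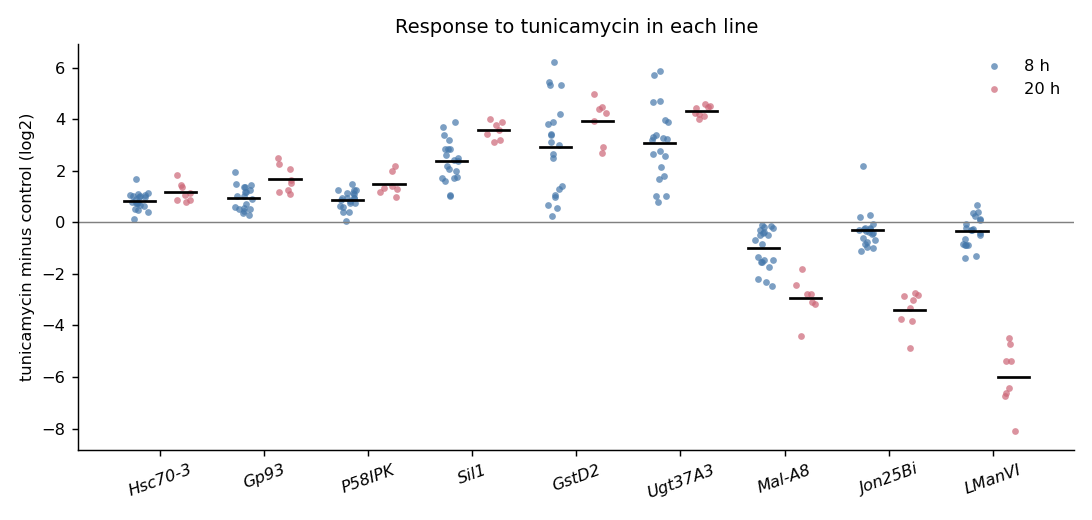
Log2 difference between tunicamycin and control for 9 genes, with 1 point per line, at 8 h (blue) and at 20 h (red), and black bars for the means. The means rose to 4.33 for Ugt37A3 and fell to −5.98 for LManVI at 20 h.

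The secretory pathway lists were also higher at 20 h, and RAL301 stood apart with an ER folding score of 1.72, against 1.14 or less in the other lines. Of 21 ER folding genes 12 rose, 19 adjusted over the list alone (median 0.75, adjusted p = 5.48e-22, but adjusted p = 0.0624 with an estimated correlation), with CaBP1 at 1.99 ± 0.17 and Ero1L at 1.78 ± 0.17. Of 21 N-glycosylation genes 11 rose, 12 adjusted over the list alone (median 0.39, adjusted p = 2.01e-09, and adjusted p = 0.107 with an estimated correlation). Of 23 ER to Golgi transport genes 12 rose, 20 adjusted over the list alone (median 0.46, adjusted p = 5.33e-17, and adjusted p = 0.0730 with an estimated correlation), led by beta'COP (1.19 ± 0.14). SrpRbeta (0.84 ± 0.15) and Sec61beta (0.48 ± 0.10) rose among 23 translocon genes, 13 adjusted over the list alone (adjusted p = 1.15e-08, and adjusted p = 0.107 with an estimated correlation). Herp and Der-2 (0.63 ± 0.11) rose among 13 degradation genes, 3 adjusted over the list alone (adjusted p = 0.00202, and adjusted p = 0.469 with an estimated correlation). BI-1 (0.74 ± 0.15) and trbl (0.47 ± 0.11) rose among 11 signalling genes, 7 adjusted over the list alone (adjusted p = 0.000375, and adjusted p = 0.229 with an estimated correlation).

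Of 26 amino acid genes, 10 tRNA synthetase genes rose at 20 h, 17 members adjusted over the list alone (median 0.40, adjusted p = 5.62e-14, and adjusted p = 0.0375 with an estimated correlation). ValRS rose by 1.07 ± 0.12 (n = 6) and AspRS by 1.05 ± 0.08. Of 44 digestive enzyme genes 28 fell and 0 rose over all genes, and 33 fell and 1 rose adjusted over the list alone (median −1.54, adjusted p = 6.39e-46, and adjusted p = 0.000261 with an estimated correlation). Mal-B1 was the 1 higher (0.58 ± 0.18). Jon44E was at −4.53 ± 0.33, and the list median was −1.61, −1.77 and −1.06 in the 3 batches. The amino acid and digestive lists were the ones whose 20 h camera call held with an estimated correlation. Under fry, which does not set a list against the other genes, 8 lists passed at 20 h. Beside both of these they were ER folding (adjusted p = 7.11e-05), ER to Golgi transport (0.000117), translocon and N-glycosylation (0.000625 each), detoxification (0.00201) and signalling (0.00716). Degradation (0.0604), starvation (0.164) and ribosomal genes (0.473) did not pass under fry. Of 42 detoxification genes 11 rose, 12 rose and 1 fell adjusted over the list alone (median 0.17, adjusted p = 7.79e-06, and adjusted p = 0.369 with an estimated correlation). The batch medians of that list were −0.00, 0.47 and −0.07, and its median was 0.06 without RAL301.

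The gastric lipase gene mag (−3.74 ± 0.28), the lipase gene Lip3 (−1.26 ± 0.25) and the sugar-response gene sug (−0.47 ± 0.10) fell among 17 starvation and insulin genes, of which 1 was higher and 3 lower adjusted over the list alone (list median −0.09, adjusted p = 0.0439, and adjusted p = 0.644 with an estimated correlation). That list did not pass without RAL208, RAL301, RAL358 or RAL375 (adjusted p up to 0.160, median −0.15 without RAL301 and 0.02 without RAL375). Ribosomal protein genes had a median of 0.20 with 0 called (adjusted p = 0.000321, and adjusted p = 0.791 with an estimated correlation), and batch medians of −0.04, 0.53 and −0.03, and did not pass with quantile scaling or without RAL301 (median 0.07, adjusted p = 0.0512). Single members were called in lists that did not pass. The small heat shock gene Hsp22 rose by 1.1 (SE 0.15, n = 7; list adjusted p = 0.286), and the hemocyte receptor gene NimC1 by 0.87 ± 0.14 (n = 7; list adjusted p = 0.955). Among antimicrobial and immune genes (list adjusted p = 0.111) the Imd inhibitor pirk rose by 1.30 ± 0.27 (n = 6), and PGRP-SC2, a peptidoglycan recognition gene, was at −2.24 ± 0.40 (n = 7). Among lipogenesis genes (list adjusted p = 0.268) SREBP rose by 0.48 ± 0.10 (n = 7) and tobi was at −0.76 ± 0.15 (n = 7). Adjusted over the list alone, heat shock genes had 1 higher and 1 lower, immune genes 2 and 1, lipogenesis genes 1 and 1, cell death genes 2 and 0, and hemocyte markers 1 and 0. Of the lists without a called member, autophagy passed with quantile scaling alone.

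**Figure D2:**
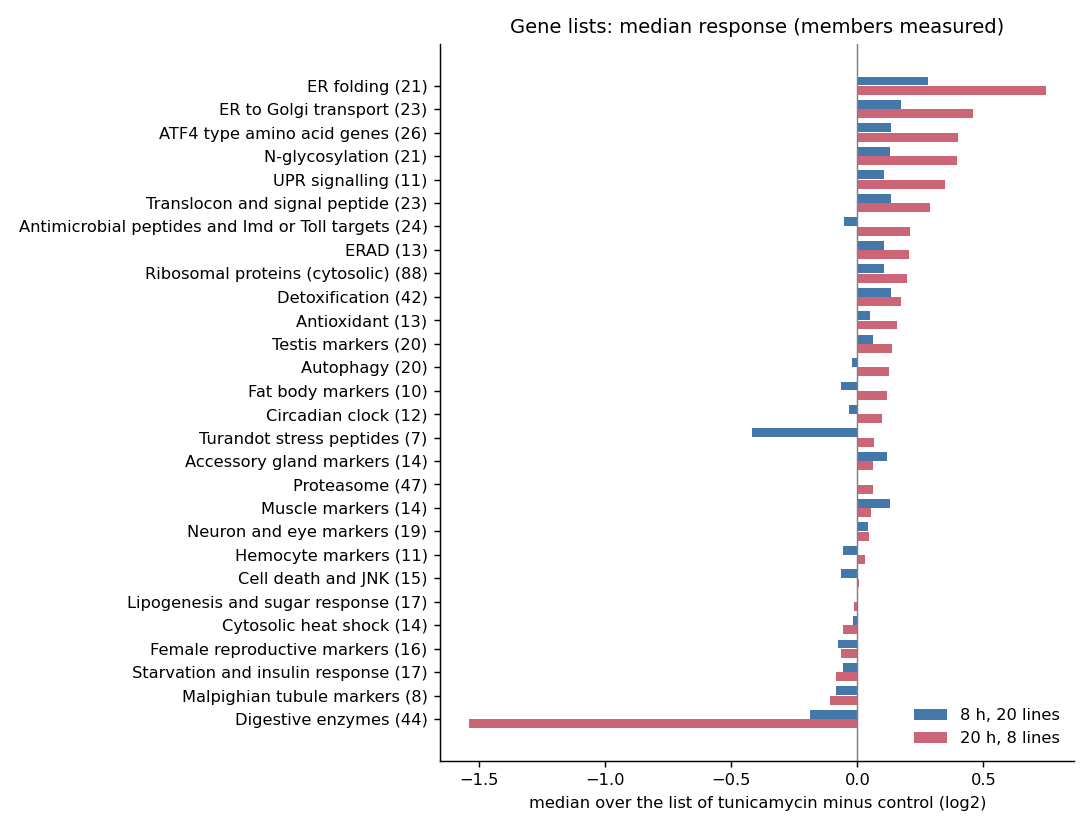
Median log2 difference between tunicamycin and control of each gene list at 8 h and at 20 h, as bars from 0, with the number of members in brackets. At 20 h the ER folding list stands at 0.75 and the digestive enzyme list at −1.54.

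The third comparison tested the change of the response between 8 h and 20 h in the 8 lines with both times, where a positive value is a higher difference at 20 h. CG14545 had the largest rise (4.56 ± 0.25, n = 6, adjusted p = 0.000215), followed by Npc1b (2.53 ± 0.28), CG7381 (2.46 ± 0.36), Ugt37C2 (1.92 ± 0.33) and the xenobiotic nuclear receptor gene Hr96 (1.28 ± 0.20, n = 7). Cyp6d2 (1.17 ± 0.19) and CG15865 (1.08 ± 0.17) completed the 7 genes that rose. The largest falls were in LManV (−5.62 ± 0.51, n = 7), Jon99Fi (−5.59 ± 0.90, n = 6), LManVI (−5.36 ± 0.27, n = 8, adjusted p = 2.27e-05), CG12057 (−4.99 ± 0.23, n = 5) and the lipase gene CG17192 (−4.96 ± 0.75, n = 7). The sterol-binding gene Npc2d was at −4.39 ± 0.26 (n = 6), the lipase gene CG6295 at −4.31 ± 0.48 (n = 7) and Diedel3 at −4.27 ± 0.48 (n = 7). LManV and LManVI code for lysosomal alpha-mannosidases.

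In all, 67 of 13481 genes changed their response, 7 upward and 60 downward, each by 1.5-fold or more. Digestive enzymes gave 14 of them, and 27 lower and 1 higher adjusted over the list alone (median −1.08, adjusted p = 7.45e-40, and adjusted p = 0.000423 with an estimated correlation), with Jon99Ci at −3.72 ± 0.25 and Mal-B1 the 1 higher (0.61 ± 0.14). This was the single list whose call held with an estimated correlation. Lists for ER folding (median 0.32, adjusted p = 9.53e-05), N-glycosylation (0.31, adjusted p = 0.000226), ER to Golgi transport (0.23, adjusted p = 0.000282) and amino acid genes (0.17, adjusted p = 0.00291) passed with 0 members called. Each of the 4 had adjusted p = 0.640 with an estimated correlation. In the batch of 4 lines their medians were 0.08, 0.06, 0.02 and 0.07, against 0.54, 0.44, 0.51 and 0.32 in the batch of 3 lines. RAL301 (ER folding score 0.587 at 8 h and 1.72 at 20 h) and RAL820 (0.170 and 1.14) had the largest rises, while the score was lower at 20 h in RAL375 (1.04 and 1.01) and RAL379 (0.754 and 0.676). Without RAL301 the medians of ER folding, transport and amino acid genes were 0.19, 0.15 and 0.10, and without RAL820 that of N-glycosylation was 0.20. Accessory gland markers had a median of −0.17 (adjusted p = 0.0269, and adjusted p = 0.732 with an estimated correlation), and did not pass with normexp background correction, with spot medians or without RAL208, RAL318, RAL358 or RAL375 (adjusted p up to 0.197, median −0.30 without RAL301 and −0.08 without RAL375), while the signalling list passed with quantile scaling alone. GstD7 (−1.20 ± 0.20) and mag (−3.16 ± 0.34) were called in lists that did not pass. Hsc70-3 (0.34 ± 0.19), Gp93 (0.32 ± 0.18), P58IPK (0.48 ± 0.20) and the other genes given whatever their values (Xbp1, crc, PEK, Ire1, Atf6, Herp, Hrd3 and Alg7) were not called, with adjusted p of 0.779 or more. Without RAL208 the count was 42, and with all 56 arrays in 1 fit 201 genes were higher and 178 lower, 65 of the 67 among them. Within batches 66 genes were called in 4 lines (6 higher, 60 lower) and 87 in 3 lines (19 higher, 68 lower).

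On control food, 20 h was compared with 8 h in the 8 lines, as the background of time on the food. Time on food and time of day cannot be separated by the labels, and all 8 h control arrays of these lines lay in slide position 1 and all 20 h ones in position 3, so that time and position cannot be told apart. The clock gene tim fell by 2.75 on the log2 scale (SE 0.21, n = 8, lower in 8 of 8 lines, adjusted p = 0.00064), and the storage protein gene Lsp2 by 2.03 (SE 0.26). The cuticle protein gene Cpr72Ec rose by 2.72 ± 0.20 (n = 7), CG17560 by 2.02 ± 0.21 (n = 7), CG14329 by 1.90 ± 0.14 (n = 7) and CG9377 by 1.88 ± 0.22. The vitamin transporter gene Smvt rose by 1.88 ± 0.10 (n = 7), the juvenile hormone esterase gene Jhe by 1.80 ± 0.18, Jhbp15 by 1.76 ± 0.27 and CG17562 by 1.73 ± 0.15. Cpr92F was at −2.56 ± 0.15 (n = 4), CG13813 at −2.04 ± 0.30 and CG34327 at −1.68 ± 0.12 (n = 5). CG33511, CG31106 and the maltase gene Mal-B1 lay between −1.02 and −0.96. CG17560 and CG17562 code for fatty acyl-CoA reductases.

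Altogether 37 genes were higher and 19 lower at 20 h on control food, and 47 changed by 1.5-fold or more (30 higher, 17 lower). With quantile scaling 45 were higher and 39 lower. Among 12 clock genes tim and Pdp1 (−0.85 ± 0.13) fell, with 3 higher and 5 lower adjusted over the list alone (adjusted p = 0.00312, and adjusted p = 0.208 with an estimated correlation). Fat body markers had a median of −0.70 with Lsp2 called, and 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.000431, and adjusted p = 0.333 with an estimated correlation). Antimicrobial peptide genes (median −0.25, adjusted p = 0.000667) and muscle markers (median −0.13, adjusted p = 0.00312) passed with 0 called, and both had adjusted p = 0.936 with an estimated correlation. Their batch medians turned in sign, with −0.12, −0.49 and 0.45 for antimicrobial peptide genes and −0.18, 0.02 and −0.10 for muscle markers. The medians were −0.14 for antimicrobial genes without RAL820, −0.19 for muscle markers without RAL301 and −0.45 for fat body markers without RAL208. No list call of this comparison held with an estimated correlation. Hemocyte and proteasome lists passed with normexp background correction, and hemocyte markers with spot medians too. ER folding genes had 0 called (median −0.04, adjusted p = 0.409). Of digestive enzymes Mal-B1 was called, with 2 higher and 1 lower adjusted over the list alone (median 0.13, adjusted p = 0.360). The count rested on few lines and on the pairing: it was 31 without RAL208, 31 without RAL358, 37 without RAL379, 35 without RAL712, 25 without the 3 lines rich in saturated spots (RAL301, RAL375 and RAL820), 14 without the 4 lines rich in outlier flags, 16 with normexp background correction and 3 without the line as a block (tim, CG17562 and CG11911, the last chosen after its values were seen). It was 92 with probes above background on every array and 103 with a trend in the variance. Within batches 14 genes were called in 4 lines (7 higher, 7 lower) and 3 in 3 lines (0 higher, 3 lower).

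Measured expression differed widely among the 20 lines at 8 h, with each gene read from 1 probe. Whether a probe matches its gene equally well in every line was not tested. The cytochrome P450 gene Cyp6a2 had the largest SD of line means (4.20 on the log2 scale, n = 20 lines, adjusted p = 3.09e-10). The genes that followed, each measured in 17 to 20 lines, were CG17134 (4.04), CG41516 (4.01), CG15184 (3.99), CG34280 (3.71), CG42326 (3.69), the cuticle gene TwdlD (3.68), Cyp6a17 (3.60, adjusted p = 6.12e-15), CG4017 (3.53) and CG15803 (3.48). Differences among lines were called for 16 of 21 ER folding genes, 11 of 13 degradation genes, 40 of 42 detoxification genes and 44 of 44 digestive enzyme genes (15, 11, 40 and 44 adjusted over the list alone). In all 13175 of 13481 genes were called in this test, which held no term for scan batch or array design. With scan day as a block 9084 were called. Both arrays of a line lay on 1 slide, and 12 lines had a slide of their own, so that line and slide cannot be told apart for these. With slide as a block, where just the 4 pairs of lines that shared a slide bear on the test, 4092 genes were called, and within batches 7474 of 13480 in 4 lines, 10815 of 13481 in 9 lines, and 52 of 7256 and 298 of 13435 in 3 lines each.

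Whether lines differed in their response was tested over both times in the 8 lines, and limma called 0 genes, with 881 at an unadjusted p below 0.05. The genes with the smallest p were CG5290, insc, CG10182, cno, Ir85a, CG7550, Sec6, CG13326, asRNA:CR33945 and Scgalpha, each with adjusted p = 0.106 and measured in 4 to 6 lines. Quantile scaling called 4 genes (CG18420, CG42382, CG5290 and insc), the mean over probes 18, a filter on every array 2 (CG5290 and insc), a trend in the variance 10, and leaving out the lines rich in saturated spots 1 (CG5290). CG18420 and CG42382 were chosen here after their values were seen. No list had a member called over all genes, and aly among testis markers and Fbp1 among fat body markers passed adjusted over the list alone. In simulated data 44.8% of genes with random line effects of SD 1 on the log2 scale were recovered in this design.

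The size of the ER folding response was then set beside that of the other lists, line by line. The ER folding score at 8 h averaged 0.518 with an SD of 0.230 over 20 lines, from 0.170 in RAL820 to 1.04 in RAL375. Both ends included an array of doubtful quality. The RAL820 control array at 8 h had 1891 saturated and 15087 outlier-flagged spots, and the RAL375 tunicamycin array 747 and 22893. The ER folding score correlated with the score of the amino acid genes (r = 0.886, permutation p = 1e-05, rho = 0.874, permutation p = 2e-05, adjusted p = 5.4e-05, n = 20), with r = 0.843 without the 2 lines farthest from the median. It also correlated with detoxification (r = 0.873, permutation p = 1e-05, rho = 0.853, permutation p = 1e-05, 0.778 without 2 lines) and ER to Golgi transport (r = 0.882, permutation p = 1e-05, rho = 0.847, permutation p = 1e-05, 0.80 without 2 lines). The p of 1e-05 is the smallest that the permutations can give. In the batch of 9 lines, the single one with at least 6, these r were 0.930, 0.834 and 0.760.

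Of 27 lists tested in this way, 14 passed after adjustment, against 8 with quantile scaling, 22 with normexp background correction and 21 with spot medians, and 8 without the lines rich in saturated spots or without those rich in outlier flags. N-glycosylation (r = 0.827, rho = 0.771), degradation (0.827, rho = 0.729), signalling (0.788, rho = 0.680), translocon (0.727, rho = 0.642) and antioxidant genes (0.726, rho = 0.693) were among them, with adjusted permutation p up to 0.00115. Within the batch of 9 lines their r were 0.638, 0.554, 0.781, −0.022 and 0.258, so that the relation with translocon and antioxidant genes did not hold there. Ribosomal, proteasome, testis, accessory gland, muscle and lipogenesis scores passed (r from 0.507 to 0.599), but rested on 2 lines, with r of 0.321 or less when these were left out. The digestive score had r = −0.318 (permutation p = 0.175, rho = −0.386) over 20 lines and r = −0.833 in the batch of 9 lines. Scores of 2 lists share their arrays, and 1000 random lists of 21 genes had a median r of 0.256 and a 95th percentile of 0.558 with the ER folding score.

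The correlation between the ER folding scores of a line at 8 h and at 20 h did not pass over the 8 lines (r = −0.275, exact permutation p = 0.437, rho = −0.524, exact permutation p = 0.197). Without the 2 lines farthest from the median r was −0.461, and no batch held 6 of these lines. The sign turned in the 4 lines of 1 batch (r = 0.079), which are also those left without the lines rich in outlier flags, and 4 lines are too few to test a relation. RAL375 had 1.04 at 8 h and 1.01 at 20 h, while RAL820 went from 0.170 to 1.14 and RAL301 from 0.587 to 1.72. The scores of a line at both times need not average the same members, since spots with outlier flags were left out.

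**Figure D3:**
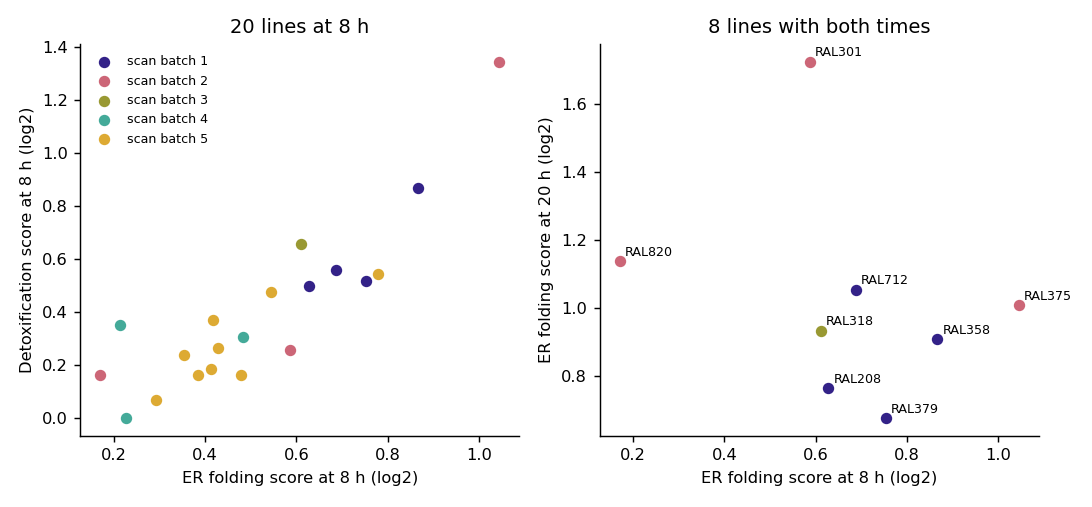
Left, the ER folding score against the detoxification score of 20 lines at 8 h (mean log2 difference of each list), coloured by scan batch. Right, the ER folding score at 8 h against that at 20 h for 8 lines, with r of 0.873 on the left and −0.275 on the right.

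The median, the mean and the camera test of a list differed in sign in 15 results, none of them past the threshold. At 8 h these were cytosolic heat shock, autophagy and lipogenesis. At 20 h they were Turandot peptides, cell death, fat body and hemocyte markers, and for the change of the response detoxification, antioxidant and cell death genes. On control food they were degradation, signalling, translocon, amino acid and testis genes.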

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

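The tests of the digestive enzyme fall and of the unlike RAL370 arrays were chosen after those patterns were seen, with the RAL370 bounds set and then revised after its values, and the decision rules for array brightness and scan batch were revised after a first run to take account of spread. The starvation list with members left out, and the count at an unadjusted p for line differences in the response, were also chosen after the first values were seen. The gut gene list was written after the digestive fall was seen but before the 20 h values of its genes were looked at, except that Duox had been seen on control food.

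At 20 h, 15 of 63 values tested had a line whose gap to its nearest neighbour was large for the range of the 8 lines, where chance gives about 1 in 20. RAL301 was the line in 13 of them. The values tested came from the same arrays and are not independent, so that 1 unusual line could give this excess. Its difference between tunicamycin and control was 5.36 for Ugt37C2, 3.73 for sel, 4.31 for CG7381, 3.98 for Npc1b, 1.23 for Xbp1 and 1.69 for Herp. Its list scores were 1.72 for ER folding, 0.80 for degradation, 0.784 for signalling, 0.528 for autophagy, 0.50 for proteasome, 0.91 for female reproductive and 0.524 for hemocyte genes. RAL820 was lowest for PEK (−0.27) and Hrd3 (−0.42). The RAL301 tunicamycin array at 20 h had 1153 saturated spots.

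Differences between the responses at the 2 times, each tested as a difference by limma, stood out for 15 genes. The response was higher at 20 h by 4.56 for CG14545, 2.53 for Npc1b, 2.46 for CG7381, 1.92 for Ugt37C2, 1.28 for Hr96, 1.17 for Cyp6d2 and 1.08 for CG15865. It differed by −5.62 for LManV, −5.59 for Jon99Fi, −5.36 for LManVI, −4.99 for CG12057, −4.96 for CG17192, −4.39 for Npc2d, −4.31 for CG6295 and −4.27 for Diedel3. The digestive enzyme list had a median change of −1.08 over 44 genes. Among 11175 probes without a gene name, which no comparison of genes used, 29 were called for tunicamycin at 8 h and 64 at 20 h.

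Digestive enzyme genes fell at 20 h, with a list median of −1.54. A loss of all gut RNA as large as the fall of the list was argued against by 21 gut genes that code for no digestive enzyme. Their median was −0.114 and their lowest value −0.76 (Myo31DF). Myo31DF and Myo61F (−0.72) fell and Sox21a (0.74) rose. How far these genes are restricted to the gut in whole flies was not tested, so that a smaller loss, or a loss of some gut cells, stays open. Array scaling or brightness was argued against by the list median, which was at most −1.46 under 4 scaling and background settings. Food deprivation may remain a candidate explanation. A rise of the starvation and insulin list had been set as its sign, and a fall with adjusted p below 0.05 as the sign against it. The camera t of that list was −2.38 (adjusted p = 0.0439, but adjusted p = 0.644 with an estimated correlation). The bound against food deprivation was thus met with the preset correlation alone, and as written it named no estimated correlation. The list mixes starvation, insulin and sugar-response genes, which need not move in the same direction, so that the sign of its t decides nothing. The t was −0.92 (adjusted p = 0.501) without the lipase genes mag and Lip3 and −1.82 (adjusted p = 0.147) without sug, so that the call needed both. Feeding was not measured, and this stays open.

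The ER folding score at 8 h ranged from 0.170 in RAL820 to 1.04 in RAL375 among 20 lines. Each end included an array with saturated spots and many outlier flags. Array brightness stays open, with r = −0.189 between the score and the log2 brightness ratio of a line's arrays (permutation p = 0.425, n = 20). Scan batch stays open, since the mean SD within batches was 0.907 of the SD over all lines, with a jackknife SE of 0.279. That mean was raised by RAL301, RAL375 and RAL820, whose batch had an SD of 0.438. The other batches with several lines had 0.103, 0.153 and 0.141. Scores ran from 0.627 to 0.866 in the batch of 4 lines and from 0.293 to 0.780 in that of 9. They ran from 0.214 to 0.484 in the batch of RAL335, RAL370 and RAL440. A lasting difference between lines also stays open: the 8 h and 20 h scores had r = −0.275 over 8 lines (exact permutation p = 0.437), which met the bound set against it but not by more than its spread, and r = 0.079 in the 4 lines without many outlier marks.

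The tunicamycin and control arrays of RAL370 at 8 h correlated with r = 0.279 in their deviations from the group means, where the lowest mean r in another line was 0.668. The highest r with an array of another of the 20 lines was 0.506. This cannot exclude an array of another line, because the arrays of a line shared a slide and the r of a line across slides is not known. The 75th percentile of the processed signal was 4026.9 on the control array and 20420.1 on the tunicamycin array. Female RNA on the control array stays open: the mean of the female reproductive list there lay below the highest of the other 19 control arrays (difference −0.353), but 1.27 above that of the tunicamycin array of the line, where the difference in the other lines ran from −3.16 to 0.61. No biological explanation was tested, and a line from outside the 20 was not tested.

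For each count of called genes, 100 arrangements of the arrays were compared, the real one included. Swapping the arrays within lines gave as many genes as the real arrangement in 1 of 100 at 8 h (175 higher and 204 lower, against 0 in the highest other), in 1 of 100 at 20 h (538 against just over 100), in 1 of 100 for the change of the response (67 against 12) and in 1 of 100 on control food (56 against 3), so that chance can be excluded for these 4. Shuffling lines gave as many as the 13175 genes of the line differences in 1 of 100, with 4356 in the highest other and a median of 2, so that chance can be excluded there too. For line differences in the response the real count was 0, which 100 of 100 arrangements must reach (104 in the highest other), so that this count decides nothing. By genes at an unadjusted p below 0.05, 35 of 100 arrangements gave as many as the real 881, with 2737 in the highest other, so that chance cannot be excluded.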

How the results depend on the processing

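Background correction on spot medians, spot medians, outlier-marked spots kept, and the leaving out of doubted lines, of list members and of each line for the scores and lists were chosen after seeing the data, and the other settings before. Normexp on mean signals was not run, and spot medians were used in its place. The deposited table was not used because its order stays unknown for 38 arrays. Signal over background limits the dim genes: 72.7% to 99.1% of spots per array were well above background. For named genes, 387 of 420 results kept their direction and side of the threshold, 23 lost the call, 3 gained it and 7 changed sign. For gene lists 815 of 899 did, 42 lost the call, 6 gained it and 36 changed sign. No result that changed sign was past the threshold after doing so. Where a count moved, the cause was not tested, except that fewer lines entered some fits.

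Without the line as a block 31 genes were called at 8 h, 139 at 20 h and 3 on control food. The pairing held the calls of 13 named genes at 8 h and 8 at 20 h, and leaving it out changed no other call of the genes named for these 2 comparisons. Slide and scan day as further blocks left the counts at 8 h and 20 h as they were, because both arrays of a line shared them. At 8 h 206 genes were called with normexp background correction (202 shared) and 152 in the 8 lines with both times (140 shared). For the change of the response, all 56 arrays in 1 fit called 3.8e+02 genes, exactly 201 higher and 178 lower. On control food the count was 92 with probes above background on every array, 103 with a variance trend, 16 with normexp, 25 without lines with saturated spots and 14 without lines with many outlier marks. Line differences numbered 4092 with slide as a block. Line differences in the response numbered 4 with quantile scaling, 18 with the mean over probes, 2 with probes above background on every array, 10 with a variance trend and 1 without lines with saturated spots, against 0. Lists called fell from 14 to 7 at 8 h, 11 to 2 at 20 h, 6 to 1 for the change and 4 to 0 on control food with an estimated correlation. In the same order fry called 11, 8, 1 and 1. Lists whose score followed ER folding numbered 8 with quantile scaling, 22 with normexp, and 8 without lines with saturated spots or with many outlier marks, against 14. The r between the 8 h and 20 h scores ran from −0.328 to −0.0879 over 4 settings and from −0.345 to −0.242 without each line in turn, and was 0.079 in the 4 lines without many outlier marks. The starvation list at 20 h lost its call without mag and Lip3 (t = −0.92), without sug (−1.82) and without all 3 (−0.27). Leaving out 1 line ended the call of that list, of ribosomal genes at 20 h and of accessory gland markers for the change. Leaving out each line in turn gave 312 to 428 genes at 8 h, 387 to 660 at 20 h, 42 to 65 for the change, 31 to 55 on control food, 13054 to 13255 for line differences and 0 to 0 for line differences in the response.

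The camera t of these lists changed sign. With quantile scaling at 8 h it was −0.0336 for heat shock, −0.124 for antioxidant, −0.326 for autophagy, −0.623 for ribosomal, −1.03 for proteasome and −1.02 for testis genes. At 20 h it was −0.283 for antioxidant, −2.18 for accessory gland, −0.525 for muscle, −0.499 for neuron and 0.0595 for hemocyte genes. For the change it was 0.483 for ribosomal and 0.175 for neuron genes, and on control food 0.654 for degradation, 0.108 for signalling, 0.608 for translocon, −0.115 for autophagy and −0.703 for female genes. With normexp it was −0.181 for heat shock, −0.299 for autophagy and −0.368 for proteasome genes at 8 h, and 0.783 for Turandot and 0.232 for hemocyte genes at 20 h. On control food it was −0.636 for detoxification, −0.174 for autophagy, −0.0463 for starvation, −0.00528 for lipogenesis and −0.206 for ribosomal genes. With spot medians it was −0.197 for heat shock and −0.0712 for autophagy genes at 8 h, and 0.505 for Turandot, −0.199 for neuron and 0.337 for hemocyte genes at 20 h. It was 0.134 for Malpighian tubule genes for the change, and 0.0714 for signalling and −0.398 for female genes on control food. Single genes changed sign as well: crc (−0.044) and Atf6 (0.015) at 8 h with quantile scaling, Atf6 with median scaling (0.027 at 8 h, −0.039 at 20 h) and with outlier-marked spots kept (−0.00124 at 20 h), and Hrd3 at 20 h with normexp (−0.010) and spot medians (−0.050).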

Other observations

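No further test was chosen for this part, and the genes named were picked after their values were seen. On control food, 8 of 12 clock genes differed between 20 h and 8 h adjusted over the list alone. Beside tim and Pdp1, the values were −1.41 ± 0.25 (SE, n = 6) for vri, −1.02 ± 0.20 (n = 5) for per and −0.55 ± 0.11 (n = 8) for cwo, all parts of the clock's negative or modulating arms. Those of Clk, its activator, the photoreceptor gene cry and the neuropeptide gene Pdf were 0.81 ± 0.13 (n = 6), 1.01 ± 0.18 (n = 7) and 0.31 ± 0.12 (n = 7). Of these 8, tim and Pdp1 also passed over all genes. Among fat body markers 1 was higher and 5 were lower adjusted over the list alone. The lower ones included the larval storage protein genes Lsp1beta (−1.49 ± 0.35, n = 7), Lsp1alpha (−1.83 ± 0.67, n = 6) and Lsp2. The camera call of that list did not hold with an estimated correlation (adjusted p = 0.333). The fat body list had a median of −0.93 in the batch of 4 lines, −0.27 in the batch of 3 and −0.47 in the single line of the other batch.

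Expression differences among the 20 lines at 8 h were called for 13175 of 13481 genes, so that a list with nearly every member called is no more than most genes show. In 15 of the 28 lists every member was called. The others had 9 of 11 signalling, 19 of 23 ER to Golgi transport, 17 of 20 testis, 43 of 47 proteasome, 25 of 26 amino acid, 13 of 14 heat shock, 12 of 13 antioxidant, 19 of 20 autophagy, 16 of 17 lipogenesis and 87 of 88 ribosomal protein genes, beside the 16 of 21 ER folding, 11 of 13 degradation and 40 of 42 detoxification genes given before. Whether any of these shares differs from that of all genes was not tested. For 12 lines these differences cannot be told apart from slides, and whether the probes match every line equally well was not tested.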
